A study of Pseudomonas aeruginosa with 9 samples.

How the data were processed

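RNA of Pseudomonas aeruginosa PA14 wildtype was measured on Affymetrix P. aeruginosa arrays, 1 array per sample, on 9 arrays in all. PA14 is a clinical isolate widely used in the laboratory, while the array was designed mainly on the genome of strain PAO1. Per the labels' protocols, cells were grown overnight in dilute R2B at 30 °C, washed, and placed in the upper chamber of a transwell in a filtered and heat-treated version of the test liquid, above the same liquid in non-sterile form. A transwell is a pair of chambers parted by a porous filter. After 3 h at 22 °C without shaking the cells were collected in an RNA-stabilising reagent, lysed with lysozyme, and their RNA was column-purified with DNase treatment on the column and again in solution. Biotinylated cDNA was made from 50 ng of whole RNA with an amplification kit, per the labels' protocols.

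The values used are the log2 summaries per probe set that the authors deposited for all 9 arrays. Affymetrix Expression Console, RMA and Transcriptome Analysis Console 2.0 are named in the submitters' processing notes, with no role or order given. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a set on the log2 scale. On the deposited values the median of each array lay between 5.02 and 5.11 and the values ran from 2.55 to 13.02, with no centring by gene. Quantile normalization sets all arrays to nearly the same distribution, so a change in the total amount of messenger RNA per cell is removed, and fold changes are relative to the other probe sets. RMA values level off near the background, so the fold changes of dim genes are understated. The 14 control probe sets had a median of 2.70 and a highest value of 3.00 on any array, and this highest value served as a mark of background. It is a low mark, since the 9 probe sets for genes that PA14 lacks had a mean of 3.50 in dilute R2B.

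Of 5896 probe sets, the 14 controls were left out and 5882 were tested: 5545 for PAO1 genes, 199 intergenic, 117 for genes of other strains and 21 for ribosomal or transfer RNA. Names came from the platform annotation paired with the RefSeq table of assembly ASM676v1: 5500 of the 5545 gene probe sets were named through these tables, 45 were not and keep the locus tag of the probe set, and 0 stood for several genes. The build behind the probe design is not given in the sources used here, so no coordinates are printed, and the table served only for names and for which genes are neighbours. Probe sets match PAO1 sequence, so a gene that PA14 lacks, or whose PA14 copy differs under the probes, reads low on every array.

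Groups were taken from the labels: dilute R2B, dilute LB Lennox, pond water and tap water. R2B is a low-nutrient broth for water bacteria and LB a rich laboratory broth; the degree to which LB was diluted is not given in the sources used here. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Every array entered 1 limma fit with a mean for each group (lmFit and eBayes, limma 3.58.1 in R 4.3.3), so all groups shared an estimate of the spread, with 9.71 degrees of freedom after moderation. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 5882 probe sets of a comparison, with calls at an adjusted p under 0.05. Fold changes are differences of group means on the log2 scale, given with their standard error (SE), and levels are log2 intensity with the SD between arrays. The number of arrays limits the precision: the median standard error of a fold change was 0.09 for comparisons with tap water and 0.10 for the others.

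A total of 35 gene lists was written before the data were examined, from general knowledge of P. aeruginosa as PAO1 locus tags, and all had at least 3 measured members. Each list was tested with limma's camera, which compares its members with all other probe sets, at the preset correlation between genes of 0.01. The camera p-values were adjusted over the 35 lists of a comparison. Beside each list stand the numbers of members that passed over all probe sets and adjusted over the list alone. Lists were tested again with a correlation estimated from the data and with fry, which tests only whether members move on balance in 1 direction. For every list called by camera, the median, the mean and the test had the same sign.

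Genes were named by a rule written before the data were examined. It took the 8 largest increases and 8 largest decreases among called probe sets whose arrays did not overlap between groups (4 and 4 for dilute LB against dilute R2B and for tap against pond water), and the 3 called members that moved furthest in the direction of each called list. Added to these in every comparison were PA3920, pcoB, czcA, PA5498, pvdS, pstS, rpoS, rmf, katA and ahpC. Other genes named in the text were chosen after their values were seen, as members of a list or neighbours in the genome.

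The scripts were tested on simulated data with 5882 probe sets and the residual spread of these arrays. For 50 changed probe sets at each size, 100% of 2-fold changes were recovered in every simulated comparison. Of 1.41-fold changes, 92% were recovered for tap water against dilute R2B, 82% for pond water against dilute R2B, 90% for dilute LB against dilute R2B and 98% for tap against pond water, with 9, 14, 9 and 13 false calls. A shifted list was recovered in each simulated comparison with 0 other lists called. Simulated probe sets were drawn independently of each other, so this does not show how camera behaves with correlated genes. The correlation estimated from the data was 0.55 for ribosomal proteins and 0.63 for ATP synthase.

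Alternatives set before the data were examined were a shift of each array to a common median, cyclic loess, leaving out probe sets whose mean lay below the 25th percentile, an intensity trend with a robust prior, array weights, a fit of the 2 compared groups alone, the replicate number as a block, leaving out each array in turn, and a limit of 2-fold. The use of dilute LB in place of dilute R2B as the control was added after seeing the data. Figures were drawn with matplotlib 3.10.9.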

Results

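Transcript levels of P. aeruginosa PA14 were measured after 3 h in 4 liquids: dilute R2B (n = 2 arrays), which the design names as the control, dilute LB (n = 2), pond water (n = 2) and tap water (n = 3). The study asked how the bacterium responds to drinking water and to fresh water from a pond. Arrays of the same liquid correlated at r = 0.993 to 0.997 across probe sets. Between liquids r was 0.979 to 0.982 for the 2 dilute media, 0.942 to 0.947 for the 2 waters, 0.860 to 0.869 for dilute R2B and tap water and 0.839 to 0.845 for dilute R2B and pond water. The first principal component, with 77.0% of the variance, separated media from waters, the second (15.8%) tap from pond water, and the third (4.38%) dilute R2B from dilute LB. On each array 98.0% to 98.3% of the tested probe sets lay above the highest control value. Errors below are the SE of a log2 fold change or the SD of a level, and all p-values are limma's, adjusted over the probe sets or the lists tested.

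In tap water, genes of copper and zinc efflux stood far above their level in dilute R2B, while genes for growth without oxygen, ribosomal proteins and ATP synthase stood below it. PA3519, a gene of a copper-responsive cluster, rose most: its level was 11.88 ± 0.02 (SD, n = 3) in tap water and 3.83 ± 0.12 (SD, n = 2) in dilute R2B, a log2 fold change of 8.06 ± 0.07 (adjusted p = 1.5e-12). Its dilute R2B level lay near the mean of 3.50 of probe sets for genes that PA14 lacks, so the change may be understated. The gene of the high-affinity cbb3 oxidase subunit ccoO2 fell most, from 11.76 ± 0.14 to 5.59 ± 0.37, a log2 fold change of -6.17 ± 0.18 (adjusted p = 1.6e-09). In all, 2644 of 5882 probe sets changed, 1273 up and 1371 down, and 952 of them by at least 2-fold (474 up, 478 down).

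All 17 measured members of the copper efflux and resistance list rose in tap water (17 adjusted over the list alone), with a median log2 fold change of 2.75 (camera adjusted p = 2.4e-14, adjusted p = 0.052 with an estimated correlation). The gene ptrA, for a copper-inducible periplasmic protein, rose 74.7-fold from a level of 4.24 in dilute R2B, and PA3516, near PA3519, at least 107-fold. The dilute R2B level of PA3516, 3.33, lay below the mean of 3.50 of the probe sets for genes that PA14 lacks. It was therefore not told apart from background there, and its fold is taken as a lower bound. PA2807 rose 55.8-fold, pcoB, a copper resistance gene, 4.21-fold, and PA3920, a copper-exporting ATPase, 6.07-fold. The zinc and cadmium efflux list rose as a whole, with 8 of 8 members up (8 adjusted over the list alone) and a median of 3.07 (camera adjusted p = 2.7e-08, adjusted p = 0.14 with an estimated correlation). Within it the response regulator PA2523 rose 56.1-fold, the pump genes czcB and czcA 13.1-fold and 10.03-fold, and the cation-exporting ATPase PA3690 11.7-fold. The zinc starvation list, which holds uptake genes that low zinc induces, had 3 members up and 3 down of 30 (3 and 2 adjusted over the list alone) and was not called (camera adjusted p = 0.89), and the zinc-binding uptake protein PA5498 had a log2 fold change of -0.28 ± 0.11 (adjusted p = 0.076).

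Denitrification and anaerobic metabolism genes fell in tap water, 37 of 40 (37 adjusted over the list alone). Their median was -1.99 (camera adjusted p = 5.1e-19, adjusted p = 0.052 with an estimated correlation). The arginine fermentation genes arcD and arcB fell 64.2-fold and 26.4-fold, and the nitrite reductase gene nirS and its neighbour PA0515 fell 24-fold and 21.2-fold. Among terminal oxidases 11 of 16 fell and 4 rose (11 and 5 adjusted over the list alone). Their median was -1.22 (camera adjusted p = 0.013, adjusted p = 0.32 with an estimated correlation). The members that fell included ccoN2 (46.6-fold) and ccoP2 (27.9-fold) and the bo3 oxidase genes cyoABCDE; those that rose were coxA, coxB and coIII of the aa3 oxidase and cioA of the cyanide-insensitive oxidase. PA3432, in none of the lists, fell 24.7-fold.

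Ribosomal protein genes fell in tap water, 52 of 54 (52 adjusted over the list alone). The median was -1.31 (camera adjusted p = 5.8e-20, adjusted p = 0.30 with an estimated correlation). The neighbours rplI, rpsR and rpsF fell most, by 8.29-fold, 7.56-fold and 7.51-fold. The probe sets for 16S and 23S ribosomal RNA were higher by 0.38 ± 0.07 and 0.37 ± 0.07 on the log2 scale, while that for 5S RNA was lower, at -0.71 ± 0.14. ATP synthase genes fell as well, 9 of 9 (9 adjusted over the list alone), led by atpH (5.48-fold), atpA (4.95-fold) and atpF (4.31-fold). Their median was -1.82 (camera adjusted p = 2.8e-06, adjusted p = 0.30 with an estimated correlation). In the TCA cycle list 13 of 16 fell and 2 rose (13 and 2 adjusted over the list alone). Its median was -0.69 (camera adjusted p = 1.7e-03, adjusted p = 0.47 with an estimated correlation). The succinate dehydrogenase genes sdhA (3.80-fold) and sdhB (2.7-fold) and the fumarase gene PA4333 (2.58-fold) fell furthest, while the aconitase gene acnA and the isocitrate dehydrogenase gene icd rose by 1.5 ± 0.10 and 1.59 ± 0.09 on the log2 scale.

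Flagellar genes mostly fell in tap water, 27 of 41 with 3 up (27 and 3 adjusted over the list alone). The median was -0.53 (camera adjusted p = 7.1e-06, adjusted p = 0.16 with an estimated correlation). The basal body gene fliF fell 4.04-fold, PA1442 3.22-fold and fliE 3.21-fold. In the PhoPQ and PmrAB list, genes of surface charge and magnesium response, 12 of 20 fell (12 adjusted over the list alone). Their median was -0.36 (camera adjusted p = 1.5e-03, adjusted p = 0.21 with an estimated correlation). Its furthest members were PA4773 (5.02-fold), pmrA (4.26-fold) and PA4774 (3.55-fold), which lie side by side or nearly so in the genome.

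Choline and glycine betaine catabolism genes rose in tap water, 14 of 24 (14 adjusted over the list alone). Their median was 0.32 (camera adjusted p = 2.8e-04, adjusted p = 0.21 with an estimated correlation). PA5378, the binding protein of a choline and betaine transporter, rose 4.29-fold, the betaine aldehyde dehydrogenase gene betB 3.24-fold and PA5396 2.96-fold. Polyhydroxyalkanoate genes, which make and bind a carbon store, rose in 4 of 5 cases (5 adjusted over the list alone), the synthase gene phaC2 by 2.85-fold, phaF by 2.19-fold and phaD by 1.91-fold. The median was 0.93 (camera adjusted p = 5.2e-03, adjusted p = 0.16 with an estimated correlation). Of the heat shock and chaperone genes 7 of 16 rose and 1 fell (9 and 1 adjusted over the list alone). Their median was 0.31 (camera adjusted p = 0.013, adjusted p = 0.47 with an estimated correlation). The membrane protease gene htpX rose 5.50-fold, PA0779 3.23-fold and the chaperonin gene groEL 2.80-fold; without dilute R2B replicate 2 this list was no longer called (adjusted p = 0.070).

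The stationary phase and ribosome hibernation list had 7 of 11 up and 1 down (7 and 3 adjusted over the list alone) and was not called by camera (adjusted p = 0.051), although the stationary-phase sigma factor gene rpoS rose 6.14-fold and the ribosome modulation factor gene rmf 5.47-fold. Among other genes named in every comparison, the peroxidase gene ahpC rose 2.03-fold, the phosphate-binding gene pstS fell 2.34-fold, the pyoverdine sigma factor gene pvdS fell 1.5-fold, and the catalase gene katA had a log2 fold change of 0.09 ± 0.08 (adjusted p = 0.44). Large increases outside the lists were those of PA1954 (70.1-fold), PA2506 (68.7-fold) and PA1027 (64.2-fold). PA2506 read 3.79 and 3.86 in dilute R2B, near the mean of 3.50 for genes that PA14 lacks, so its fold may be understated.

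The lists not called in tap water by camera, with members up and down of those measured, were quorum sensing products (12 and 3 of 41), oxidative stress (7 and 2 of 18), amino acid biosynthesis (15 and 11 of 38), amino acid catabolism (10 and 17 of 39), NADH dehydrogenase I (0 and 8 of 13), type IV pili (3 and 11 of 32), phosphate starvation (4 and 7 of 34), and heme uptake and other iron starvation genes (6 and 4 of 27). Adjusted over the list alone these counts were 12 and 3, 7 and 2, 15 and 12, 10 and 18, 0 and 9, 3 and 11, 4 and 7, and 6 and 4. Fewer members moved among pyoverdine (2 and 4 of 21), sulfur starvation (2 and 5 of 29), osmoadaptation (4 and 2 of 18), glucose uptake and the Entner-Doudoroff pathway (4 and 2 of 14), nitrogen limitation (3 and 1 of 15), the pyocins (4 and 1 of 39), biofilm matrix (4 and 0 of 35), multidrug efflux (3 and 1 of 16), the SOS response (2 and 2 of 13), type III secretion (0 and 2 of 38), pyochelin (2 and 0 of 12) and type VI secretion cluster H1 (1 and 0 of 18). Adjusted over the list alone these were 2 and 3, 2 and 4, 4 and 2, 4 and 2, 3 and 1, 4 and 0, 3 and 0, 3 and 1, 2 and 2, 0 and 1, 1 and 0, and 0 and 0. Of 9 probe sets for genes that PA14 lacks, which were taken to mark background, 1 fell (1 adjusted over the list alone). The lowest log2 fold change among them was -0.57, so not all 9 need read background alone and their mean is a rough mark. With an estimated correlation 0 of the 12 called lists passed (7 lists had an unadjusted p under 0.05), and with fry all 12 passed among 24.

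**Figure D1:**
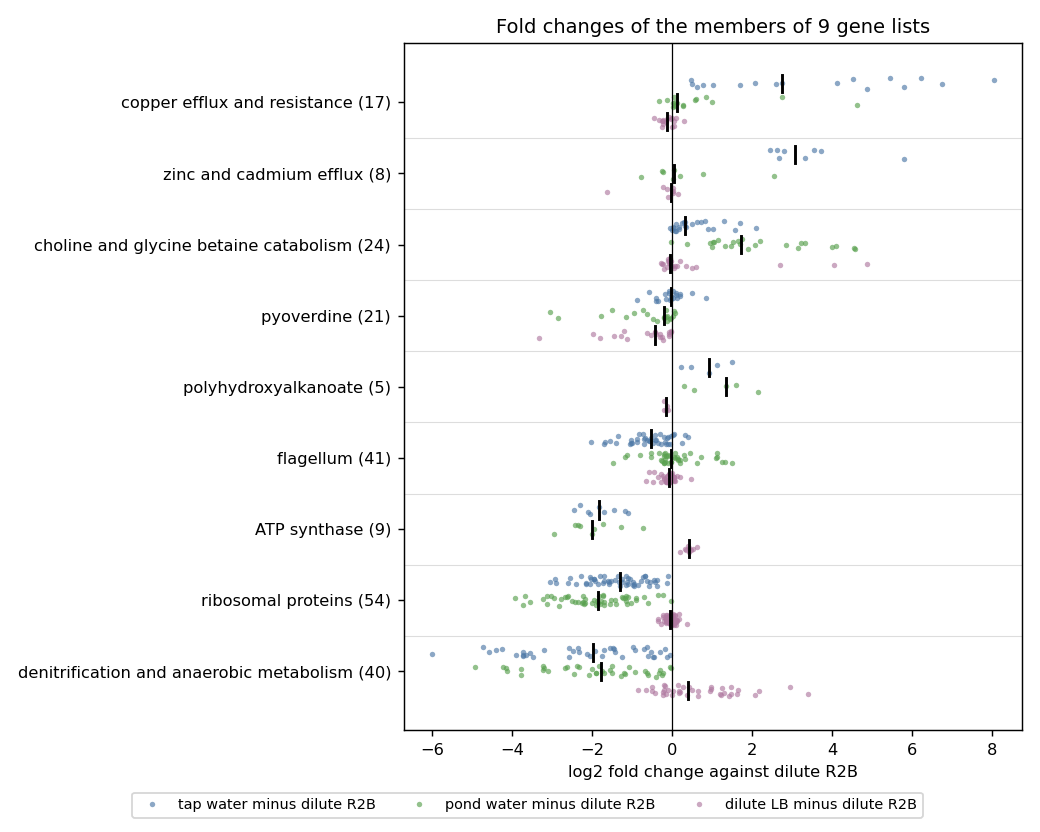
Log2 fold change against dilute R2B (horizontal axis) of each measured member of 9 gene lists, with the number of members in brackets; points are probe sets in tap water, pond water and dilute LB, and black bars are the list medians. The copper list has a median of 2.75 in tap water and 0.13 in pond water, while the ribosomal list lies at -1.31 and -1.86 in the waters and -0.05 in dilute LB.

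In pond water, genes of glycine betaine catabolism stood above their level in dilute R2B, and ribosomal protein, anaerobic and ATP synthase genes stood below it. The lipase gene lipA rose most, from 5.18 ± 0.19 (SD, n = 2) to 11.55 ± 0.15 (SD, n = 2), a log2 fold change of 6.37 ± 0.11 (adjusted p = 1.1e-10). The gene of the arginine-ornithine exchanger arcD fell most, from 11.60 ± 0.12 to 6.67 ± 0.25, a log2 fold change of -4.93 ± 0.13 (adjusted p = 1.2e-09). In all, 2790 probe sets changed, 1356 up and 1434 down, and 1080 of them by at least 2-fold (497 up, 583 down).

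Choline and glycine betaine catabolism genes rose in pond water, 23 of 24 (23 adjusted over the list alone). Their median was 1.72 (camera adjusted p = 3.4e-13, adjusted p = 0.064 with an estimated correlation). The glycine betaine demethylase gene gbcA rose 23.9-fold, PA5396 23.4-fold and PA5378 17.2-fold. All 5 polyhydroxyalkanoate genes rose (5 adjusted over the list alone): phaC2 by 4.44-fold, phaF by 3.04-fold and phaD by 2.55-fold. The median was 1.35 (camera adjusted p = 5.4e-03, adjusted p = 0.23 with an estimated correlation). In the copper list 8 of 17 rose and 1 fell (8 and 1 adjusted over the list alone). Their median was 0.13 (camera adjusted p = 0.026, adjusted p = 0.44 with an estimated correlation). The rise lay mainly with PA3519 (24.5-fold), PA3516 (at least 6.73-fold) and PA3518 (1.99-fold), while pcoB had a log2 fold change of 0.13 ± 0.11 (adjusted p = 0.40) and PA3920 of -0.33 ± 0.11 (adjusted p = 0.034). The copper list was no longer called without dilute R2B replicate 1 (adjusted p = 0.055), and PA3920 no longer passed with cyclic loess, array weights or the replicate block or when dilute R2B replicate 2 or either pond water array was left out.

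Ribosomal protein genes fell in pond water, 52 of 54 (53 adjusted over the list alone). Their median was -1.86 (camera adjusted p = 3.1e-23, adjusted p = 0.42 with an estimated correlation). The genes rpsI, rpsR and rpsP fell 15.1-fold, 13.1-fold and 12.7-fold. As in tap water, 16S and 23S RNA probe sets were higher, at 0.41 ± 0.08 and 0.46 ± 0.07, and that of 5S RNA lower, at -0.74 ± 0.15. ATP synthase genes fell in 9 of 9 cases (9 adjusted over the list alone), atpH by 7.71-fold, atpA by 5.42-fold and atpF by 5.10-fold. The median was -2.0 (camera adjusted p = 6.1e-06, adjusted p = 0.42 with an estimated correlation). TCA cycle genes fell in 13 of 16 cases with 2 up (13 and 2 adjusted over the list alone). Their median was -0.92 (camera adjusted p = 5.3e-04, adjusted p = 0.45 with an estimated correlation). There sdhA fell 4.82-fold, PA4333 3.02-fold and sdhB 2.7-fold.

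Denitrification and anaerobic metabolism genes fell in pond water, 36 of 40 (36 adjusted over the list alone), among them PA0515 (18.8-fold) and nirS (17.7-fold). Their median was -1.79 (camera adjusted p = 3.1e-16, adjusted p = 0.064 with an estimated correlation). Terminal oxidase genes fell in 11 of 16 cases and rose in 4 (11 and 5 adjusted over the list alone). The median was -1.06 (camera adjusted p = 0.045, adjusted p = 0.44 with an estimated correlation). The cbb3 genes ccoO2, ccoN2 and ccoP2 fell 25.1-fold, 22.8-fold and 11.1-fold, and the aa3 genes coxA, coxB and coIII rose by at least 2.71, by 2.73 ± 0.12 and by 3.76 ± 0.10 on the log2 scale. The dilute R2B level of coxA, 3.35, lay below the mean of 3.50 of the probe sets for genes that PA14 lacks, so its change is taken as a lower bound. Without pond water replicate 1 the oxidase list was no longer called (adjusted p = 0.068).

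Pyoverdine genes, for the main siderophore, fell in 10 of 21 cases (10 adjusted over the list alone). Their median was -0.19 (camera adjusted p = 6.3e-03, adjusted p = 0.45 with an estimated correlation). The sigma factor gene pvdS fell 8.25-fold, the receptor gene fpvA 7.28-fold and pvdN 3.45-fold. PhoPQ and PmrAB genes fell in 9 of 20 cases (9 adjusted over the list alone), with PA4773 lower by 4.54-fold, pmrA by 4.03-fold and PA4774 by 3.73-fold. Their median was -0.24 (camera adjusted p = 6.3e-03, adjusted p = 0.42 with an estimated correlation). Among the genes named throughout, rpoS rose 9.28-fold, rmf 5.00-fold, ahpC 2.10-fold and katA 1.38-fold, and pstS fell 3.53-fold. The zinc pump gene czcA had a log2 fold change of 0.19 ± 0.09 (adjusted p = 0.10), and the zinc efflux list had 2 members up and 2 down of 8 (2 and 2 adjusted over the list alone; camera adjusted p = 0.81).

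The 8 largest increases in pond water lay outside the lists; besides lipA these were the pyrimidine catabolism gene PA0439 (80.0-fold), PA1260 (71.7-fold), the cofactor precursor gene pqqA (49.6-fold), PA1761 (44.9-fold), PA1954 (42.7-fold), PA1763 (42.4-fold) and PA3923 (40.8-fold). The dilute R2B levels of PA3923, 2.99, and of pqqA, 3.15, lay at or next to the highest control value of 3.00, so these changes are set against background and their folds are lower bounds. Decreases outside the called lists were those of the aspartate ammonia-lyase gene aspA (21.3-fold), PA3432 (21.0-fold) and the iron transport gene PA4359 (18.5-fold). Of the 10 lists called in pond water, 3 up and 7 down, 0 passed with an estimated correlation (3 lists had an unadjusted p under 0.05) and all 10 passed with fry, among 25.

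Of the lists not called in pond water, heme uptake and other iron starvation genes had 3 up and 11 down of 27 (4 and 11 adjusted over the list alone; camera adjusted p = 0.0505) and quorum sensing products 16 up and 4 down of 41 (16 and 5 adjusted over the list alone; camera adjusted p = 0.0505). Heat shock and chaperone genes had 3 up and 9 down of 16 (3 and 10 adjusted over the list alone) with a median of -0.33 (camera adjusted p = 0.12). The counts up and down were 10 and 7 of 41 for the flagellum, 10 and 18 of 39 for amino acid catabolism, 13 and 16 of 38 for amino acid biosynthesis, 5 and 9 of 32 for type IV pili, 8 and 2 of 18 for oxidative stress, 3 and 7 of 34 for phosphate starvation, 4 and 6 of 29 for sulfur starvation, 8 and 2 of 39 for the pyocins, 1 and 7 of 13 for NADH dehydrogenase I, 3 and 5 of 14 for glucose uptake and 5 and 2 of 11 for stationary phase. Adjusted over the list alone these were 10 and 7, 10 and 18, 13 and 17, 5 and 9, 8 and 2, 2 and 7, 4 and 5, 6 and 2, 1 and 8, 5 and 5, and 5 and 2. Fewer members moved in nitrogen limitation (5 and 1 of 15), osmoadaptation (3 and 3 of 18), type III secretion (3 and 3 of 38), biofilm matrix (5 and 0 of 35), type VI secretion cluster H1 (4 and 0 of 18), the SOS response (3 and 1 of 13), zinc starvation (3 and 0 of 30), multidrug efflux (2 and 1 of 16), pyochelin (0 and 1 of 12) and the genes that PA14 lacks (0 and 1 of 9). Adjusted over the list alone these were 5 and 1, 3 and 3, 1 and 0, 5 and 0, 3 and 0, 2 and 1, 2 and 0, 1 and 0, 0 and 0, and 0 and 1.

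Tap and pond water were compared directly, which tests the difference between their effects against the shared control. Genes of copper and zinc efflux were higher in tap water and genes of glycine betaine catabolism and the flagellum were higher in pond water. The largest differences were those of ptrA, at 10.46 ± 0.12 (SD, n = 3) in tap and 4.11 ± 0.10 (SD, n = 2) in pond water (log2 fold change 6.35 ± 0.12, adjusted p = 2.0e-10), and gbcA, at 5.68 ± 0.12 and 9.24 ± 0.08 (log2 fold change -3.56 ± 0.09, adjusted p = 1.9e-09). In all, 1586 probe sets differed, 805 higher in tap and 781 higher in pond water, and 334 of them by at least 2-fold (171 and 163).

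The copper list was higher in tap water for 16 of 17 members (16 adjusted over the list alone). The median was 2.93 (camera adjusted p = 9.3e-21, adjusted p = 0.025 with an estimated correlation). Besides ptrA, PA2807 was 46.2-fold higher, the copper oxidase gene pcoA 41.4-fold, PA3920 7.62-fold and pcoB 3.85-fold. Zinc and cadmium efflux genes were higher for 7 of 8 (7 adjusted over the list alone): PA2523 by 66.6-fold, PA3690 by 20.2-fold, czcB by 13.0-fold and czcA by 8.79-fold. Their median was 3.01 (camera adjusted p = 1.6e-10, adjusted p = 0.065 with an estimated correlation). PA3410, which encodes a sigma factor of the heme acquisition locus and is in none of the lists, was 46.4-fold higher.

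Choline and glycine betaine catabolism genes were lower in tap than in pond water for 23 of 24 members (23 adjusted over the list alone), among them PA5397 (10.5-fold) and PA5396 (7.91-fold). Their median was -1.33 (camera adjusted p = 7.5e-20, adjusted p = 0.025 with an estimated correlation). Flagellar genes were lower for 29 of 41 (30 adjusted over the list alone): the rod gene flgC by 3.13-fold and the hook junction genes flgL and flgK by 2.94-fold and 2.53-fold. The median was -0.50 (camera adjusted p = 2.9e-13, adjusted p = 0.036 with an estimated correlation). In denitrification and anaerobic metabolism 14 of 40 were lower (14 lower and 1 higher adjusted over the list alone), arcB by 2.81-fold, adhA by 2.75-fold and hemN by 2.34-fold. Their median was -0.14 (camera adjusted p = 4.0e-03, adjusted p = 0.35 with an estimated correlation). Terminal oxidase genes were lower for 6 of 16 (6 adjusted over the list alone). Their median was -0.15 (camera adjusted p = 4.0e-03, adjusted p = 0.28 with an estimated correlation). These included ccoO2 (2.86-fold), ccoP2 (2.53-fold) and coxA (2.42-fold), so members that fell and members that rose against dilute R2B were both lower in tap water.

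Part of the iron starvation genes were higher in tap than in pond water. Pyoverdine genes were higher for 10 of 21 (11 adjusted over the list alone): pvdS by 5.49-fold, fpvA by 3.95-fold and pvdA by 3.21-fold. The median was 0.32 (camera adjusted p = 1.2e-06, adjusted p = 0.24 with an estimated correlation). The mean level of this list was 5.82 in dilute R2B, 5.06 in dilute LB, 5.77 in tap water and 5.14 in pond water. Against dilute R2B it was not called in tap water (camera adjusted p = 0.85), so against that control the difference lay mainly in the fall in pond water. The dilute LB level lay near that of pond water, so whether pond water was low or tap water high depends on the control medium. Heme uptake and other iron starvation genes were higher for 10 of 27 (11 adjusted over the list alone), among them PA4515 (8.94-fold), the ferredoxin gene PA3530 (6.99-fold), which acts in release of stored iron, and tonB1 (4.04-fold). Their median was 0.07 (camera adjusted p = 9.8e-04, adjusted p = 0.18 with an estimated correlation). Against dilute R2B 6 of these 27 were up and 4 down in tap water, and 3 up and 11 down in pond water. The mean level of these genes was 5.61 in dilute R2B, 5.05 in dilute LB, 5.06 in pond water and 5.52 in tap water. Here too pond water lay near dilute LB. The pyochelin list, for a second siderophore, had 2 of 12 higher (2 adjusted over the list alone) and was not called (camera adjusted p = 0.17). The bacterioferritin gene bfrB, for an iron store, was 11.5-fold lower in tap water, as was PA0952, of no list, by 10.6-fold. Against dilute R2B bfrB had log2 fold changes of -1.65 in tap water and 1.88 in pond water, so both sides enter its difference.

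Ribosomal protein genes were higher in tap than in pond water for 43 of 54 and lower for 2 (44 and 2 adjusted over the list alone), rpsI by 2.87-fold, rpmH by 2.61-fold and rpmG by 2.43-fold. Their median was 0.54 (camera adjusted p = 3.7e-15, adjusted p = 0.39 with an estimated correlation). Heat shock and chaperone genes were higher for 12 of 16 (12 adjusted over the list alone): htpX by 5.13-fold, groEL by 3.40-fold and the protease gene hslU by 3.35-fold. In this list 7 members were up against dilute R2B in tap water and 9 down in pond water, so both sides enter the difference. The median was 0.97 (camera adjusted p = 3.2e-09, adjusted p = 0.18 with an estimated correlation). TCA cycle genes were higher for 7 of 16 (8 adjusted over the list alone), led by idh (1.51-fold), icd (1.42-fold) and mqoB (1.37-fold). Their median was 0.21 (camera adjusted p = 7.9e-03, adjusted p = 0.65 with an estimated correlation). The glucose and Entner-Doudoroff list had 6 of 14 higher and 2 lower (6 and 2 adjusted over the list alone): gapA by 2.27-fold, zwf by 2.27-fold and PA2322 by 1.55-fold. Its median was 0.14 (camera adjusted p = 0.049, adjusted p = 0.53 with an estimated correlation). The TCA cycle call ended with cyclic loess (adjusted p = 0.38), and the glucose call with cyclic loess, with the replicate block, or without pond water replicate 1 or tap water replicate 1 or 3 (adjusted p of 0.055 to 0.17).

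Of the genes named throughout, pstS was 1.51-fold higher in tap than in pond water, rpoS 1.51-fold lower and katA 1.30-fold lower. The log2 fold changes of rmf (0.13 ± 0.13, adjusted p = 0.55), ahpC (-0.04 ± 0.10, adjusted p = 0.81) and PA5498 (-0.27 ± 0.11, adjusted p = 0.11) did not pass. For katA the call ended without pond water replicate 1 (adjusted p = 0.056).

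Among lists not called between the waters, polyhydroxyalkanoate genes were lower in tap water for 4 of 5 (4 adjusted over the list alone; camera adjusted p = 0.068). The counts higher and lower in tap water were 10 and 5 of 38 for amino acid biosynthesis, 3 and 11 of 39 for amino acid catabolism, 2 and 8 of 41 for quorum sensing products, 3 and 6 of 32 for type IV pili, 4 and 3 of 11 for stationary phase, 4 and 2 of 18 for osmoadaptation and 2 and 1 of 9 for ATP synthase (10 and 6, 5 and 12, 2 and 8, 3 and 6, 4 and 3, 4 and 2, and 2 and 1 adjusted over the list alone). In each of the other lists not called, at most 5 members passed.

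**Figure D2:**
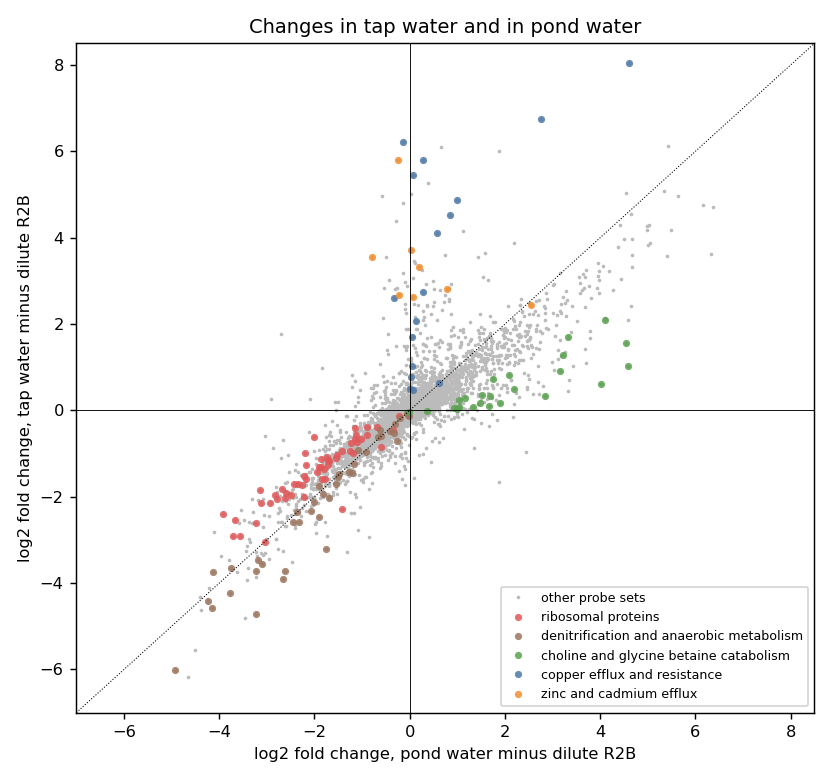
Log2 fold change of each tested probe set against dilute R2B in pond water (horizontal axis) and tap water (vertical axis), with 5 gene lists in colour; the dotted line marks equal changes. The 17 copper genes and 7 of the 8 zinc efflux genes lie above the line, with list medians of 2.75 and 3.07 in tap water and 0.13 and 0.04 in pond water, and betaine genes below it, with medians of 0.32 and 1.72.

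The changes in both waters against the same dilute R2B arrays overlapped. Of the probe sets called, 963 were up in both waters and 1164 down in both, 2127 in all in the same direction, and 65 went opposite ways. Independent lists of the same lengths would share 293 up and 334 down, and unchanged groups simulated against the same control arrays shared 0.02 on average (at most 1 in 100 draws). Across probe sets the fold changes correlated at r = 0.82, against 0.54 in the simulation, with a covariance of 0.736 against 0.00582, and 81.9% had the same sign against 68.3%. With 2 control arrays the controls could not be split into parts of at least 2 arrays each, so part of the excess of calls over independent lists may come from the shared controls. The covariance is less open to this, since shared controls add the same covariance with or without effects. The simulated groups had no effects, so their r, their share of signs and their shared calls are no baseline for groups that changed. An r below the simulated one is therefore not a sign of opposed responses. For tap water and dilute LB 232 calls went in the same direction and 231 in opposite ones (r = -0.02, against 0.55 in the simulation), and for pond water and dilute LB 236 and 242 (r = -0.01, against 0.50). The covariances of these pairs were -0.0046 and -0.0039, against 0.0058 in the simulation for each, and 54.4% and 50.3% of probe sets had the same sign, against 68.4% and 66.6%.

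Dilute LB differed from dilute R2B in far fewer probe sets than the waters did, and the genes that differed furthest included some of choline oxidation, the PhoPQ response, nitric oxide reduction and iron uptake. The genes betB and betI, the dehydrogenase and repressor of the choline operon, rose 29.1-fold and 16.6-fold. Their levels were 11.01 ± 0.04 (SD, n = 2) and 9.80 ± 0.04 in dilute LB and 6.15 ± 0.32 (SD, n = 2) and 5.74 ± 0.04 in dilute R2B (adjusted p = 4.0e-08 and 8.0e-09). The choline and glycine betaine list as a whole was not called (camera adjusted p = 0.076), with 5 of 24 up (5 adjusted over the list alone) and a median of -0.04. The gene pvdS fell most, from 9.21 ± 0.25 to 5.89 ± 0.08, a log2 fold change of -3.32 ± 0.12 (adjusted p = 1.2e-07). In all, 623 probe sets changed, 352 up and 271 down, and 107 of them by at least 2-fold (66 and 41).

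Pyoverdine genes fell in dilute LB in 11 of 21 cases (14 adjusted over the list alone), fpvA by 3.96-fold and pvdE by 3.50-fold. The median was -0.43 (camera adjusted p = 1.1e-10, adjusted p = 0.12 with an estimated correlation). Heme uptake and other iron starvation genes fell in 8 of 27 cases (10 adjusted over the list alone): the siderophore receptor gene PA4514 by 8.73-fold, the heme receptor gene phuR by 6.61-fold and PA4515 by 3.94-fold. Their median was -0.22 (camera adjusted p = 3.1e-08, adjusted p = 0.12 with an estimated correlation). PA4517, near PA4514, fell 7.73-fold. Denitrification and anaerobic metabolism genes rose in 21 of 40 cases and fell in 4 (22 and 5 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 1.1e-10, adjusted p = 0.12 with an estimated correlation). The nitric oxide reductase genes norB and norC rose 10.6-fold and 7.75-fold and PA0513, of heme biosynthesis for nitrite reductase, 4.50-fold. The dilute R2B arrays read 5.96 and 4.92 for norB, against 8.87 and 8.83 in dilute LB, so the size of its fold depends on the control array. The members that fell were narH, narJ and narK1 of the nitrate reductase cluster and PA3309.

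PhoPQ and PmrAB genes rose in dilute LB in 5 of 20 cases (6 up and 1 down adjusted over the list alone): oprH by 10.7-fold, its neighbour phoP by 2.27-fold and PA4773 by 1.69-fold. The median was 0.23 (camera adjusted p = 1.1e-04, adjusted p = 0.12 with an estimated correlation). Quorum sensing products fell in 8 of 41 cases (9 adjusted over the list alone), PA0122 by 2.16-fold, the cyanide synthase gene hcnC by 2.00-fold and the regulator gene rhlR by 1.85-fold. Their median was -0.11 (camera adjusted p = 1.6e-04, adjusted p = 0.12 with an estimated correlation). Terminal oxidase genes fell in 5 of 16 cases (5 adjusted over the list alone); these were the bo3 genes, cyoC by 2.18-fold, cyoB by 2.16-fold and cyoA by 1.96-fold, with cyoD and cyoE. Their median was -0.12 (camera adjusted p = 1.5e-03, adjusted p = 0.23 with an estimated correlation). Sulfur starvation genes fell in 3 of 29 cases (3 adjusted over the list alone): PA3931 by 1.91-fold, sbp by 1.41-fold and cysI by 1.36-fold. The median was -0.11 (camera adjusted p = 0.012, adjusted p = 0.12 with an estimated correlation).

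The other lists called in dilute LB had small medians, from -0.07 to 0.41. ATP synthase genes rose in 4 of 9 cases (7 adjusted over the list alone), atpD by 1.43-fold, atpH by 1.39-fold and atpC by 1.33-fold. Their median was 0.41 (camera adjusted p = 4.7e-05, adjusted p = 0.37 with an estimated correlation). In the TCA cycle 2 of 16 rose (3 adjusted over the list alone), acnA by 1.53-fold and sucD by 1.35-fold. Its median was 0.19 (camera adjusted p = 1.9e-04, adjusted p = 0.37 with an estimated correlation). The type III secretion list had 4 of 38 up (4 adjusted over the list alone), pscE by 1.63-fold, PA1701 by 1.51-fold and pcrV by 1.38-fold. The median was 0.06 (camera adjusted p = 0.048, adjusted p = 0.43 with an estimated correlation). Phosphate starvation had 1 of 34 down, glpQ by 1.29-fold (0 adjusted over the list alone). Its median was -0.07 (camera adjusted p = 0.048, adjusted p = 0.20 with an estimated correlation). None of the 13 NADH dehydrogenase I genes passed singly, also adjusted over the list alone (4 at an unadjusted p under 0.05), and their median was 0.17 (camera adjusted p = 0.012, adjusted p = 0.44 with an estimated correlation). Ribosomal protein genes had a median of -0.05 with 0 of 54 called by limma (0 adjusted over the list alone; 1 up and 2 down at an unadjusted p under 0.05), and that list was not called (camera adjusted p = 0.53).

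Among lists not called in dilute LB, the flagellar list had 1 up and 5 down of 41 (1 and 5 adjusted over the list alone; camera adjusted p = 0.0505), amino acid catabolism 1 up and 7 down of 39 (2 and 8 adjusted over the list alone) and the copper list 0 up and 2 down of 17 (0 and 3 adjusted over the list alone). In each of the other lists not called, at most 5 members passed.

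Among the genes named throughout, katA rose 1.43-fold and ahpC 1.32-fold in dilute LB, rpoS fell 1.43-fold and PA3920 1.37-fold. The log2 fold changes of pcoB (-0.23 ± 0.11, adjusted p = 0.25), czcA (-0.12 ± 0.09, adjusted p = 0.49), rmf (0.05 ± 0.14, adjusted p = 0.91), pstS (-0.30 ± 0.10, adjusted p = 0.097) and PA5498 (0.27 ± 0.12, adjusted p = 0.24) did not pass. The count of changed probe sets rests on the shared estimate of spread and on both dilute LB arrays: it was 300 with only these 2 groups in the fit, 365 without dilute LB replicate 1 and 357 without replicate 2. Of the 12 lists called, 6 up and 6 down, 0 passed with an estimated correlation (7 lists had an unadjusted p under 0.05) and 9 passed with fry.

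**Figure D3:**
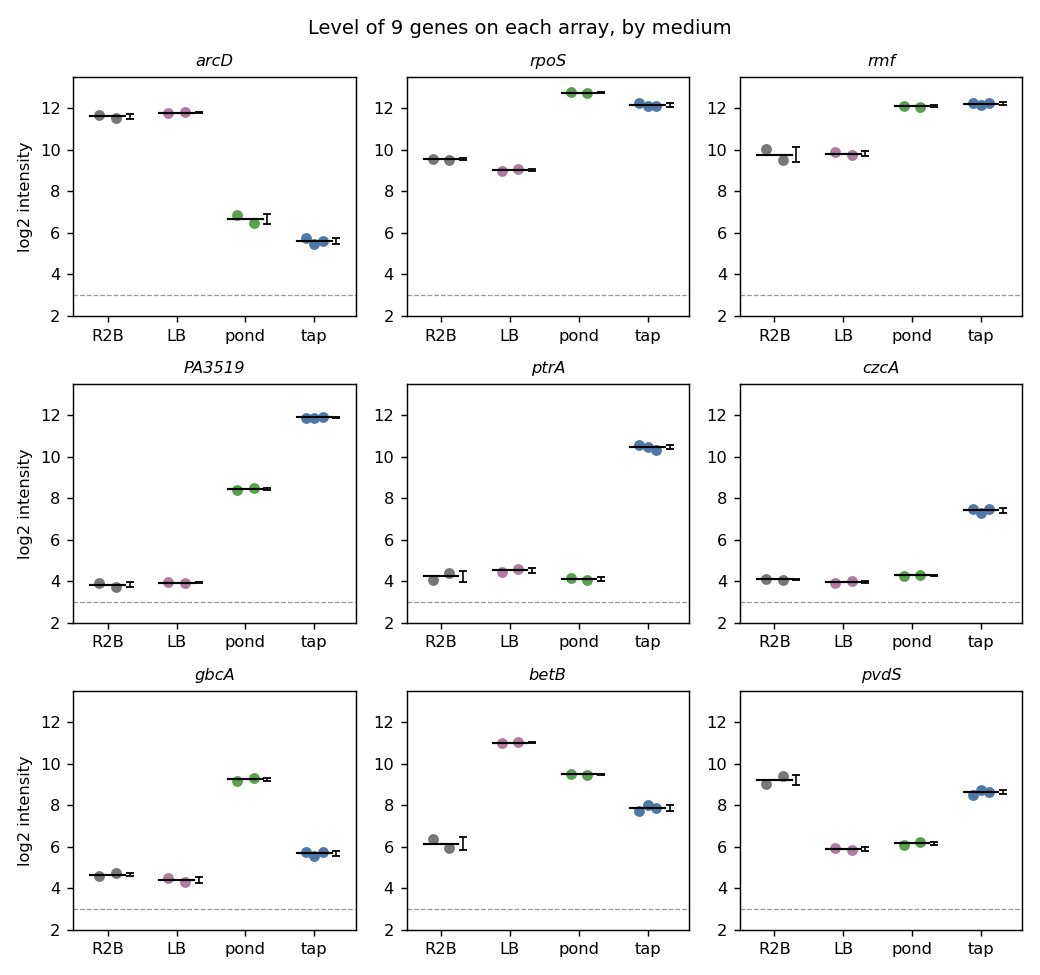
Log2 intensity (vertical axis) of 9 genes on each array of dilute R2B, dilute LB, pond water and tap water; points are arrays, lines are means, bars the SD, and the dashed line the highest control value of 3.00. The copper gene ptrA is high in tap water alone (10.46, against 4.11 to 4.53 in the other liquids), rpoS is high in both waters (12.15 and 12.74), and betB is highest in dilute LB (11.01).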

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

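The settings described here were chosen before the data were examined, except the use of dilute LB as the control, which was chosen after seeing the data. The counts of changed probe sets stayed within 1.5 times their value with a median shift, cyclic loess, the filter on dim probe sets, the trend with a robust prior, array weights and the replicate block, and no call in these settings turned direction. No scaling moved the median of all probe sets by over 0.1 on the log2 scale or the share of increases by over 10 percentage points. With a limit of 2-fold the counts were 952 for tap water and 1080 for pond water against dilute R2B, 107 for dilute LB and 334 for tap against pond water. Calls shared in the same direction then numbered 753 for both waters, 28 for tap water and dilute LB and 34 for pond water and dilute LB; the limit itself lowers these counts. A fit of the 2 compared groups alone gave 300 for dilute LB, where 2 arrays in each group leave fewer degrees of freedom, and 47.5% of the calls were kept. Leaving out 1 array gave 2351 to 2510 for tap water, 2425 to 2719 for pond water, 357 to 681 for dilute LB and 1178 to 1517 for tap against pond water; a group left with 1 array is assumed to vary like the others. For dilute LB the count was 365 without its replicate 1 and 357 without its replicate 2. Against dilute LB in place of dilute R2B, 2780 probe sets changed in tap water and 2959 in pond water; 83.7% and 86.6% of the calls against dilute R2B were kept and 21 and 28 were called in the opposite direction.

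The lists depended most on how the correlation between genes was treated. With a correlation estimated from the data, 0 lists passed in the comparisons of tap water, pond water and dilute LB with dilute R2B and 3 passed between the waters, the copper, betaine and flagellar lists. Fry called 24, 25 and 19 lists for tap water, pond water and tap against pond water. Leaving out 1 array gave 12 to 13, 10 to 11, 9 to 13 and 11 to 12 lists. Of the lists called in dilute LB, phosphate starvation, type III secretion and NADH dehydrogenase I each lost the call when some single array was left out, and the latter 2 and the TCA cycle also with fry (adjusted p of 0.069, 0.10 and 0.054). Named genes that lost the call in some setting lay mostly in dilute LB, with small changes (glpQ, pcrV, hcnC, PA3931, sbp, cysI, atpH, atpC, sucD, cyoC, ahpC and PA3920); the cause was not tested. For PA5498 the call was gained in tap water with the median shift or without tap water replicate 2, and against pond water with array weights or without pond water replicate 2, and for pstS in dilute LB with cyclic loess.

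Replicate numbers in the labels could pair arrays across groups. Deviations of same-numbered arrays from their group means correlated at -0.16 to 0.29, the highest for replicate 2 of dilute R2B and tap water. In groups of 2 arrays the deviations mirror each other, so some of these values repeat. A pairing of arrays was therefore neither shown nor excluded. With the replicate number as a block the counts were 2435, 2717, 558 and 1278 probe sets and 13, 10, 13 and 11 lists, in the order tap water, pond water, dilute LB and tap against pond water. Between tap and pond water 79.1% of the calls were then kept. RMA values near background limit what can be seen for dim genes.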

Other observations

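The groups of genes below were all chosen after their values were seen. Those called runs are at least 4 neighbours with a log2 fold change of 2 or more in the same direction, and the others were picked by hand for their function or their values. Tests of the dilute R2B arrays, of a single tap water array and of zinc were also chosen after the result was seen. Of the probe sets changed at least 2-fold, 750 of 952 in tap water and 862 of 1080 in pond water lay outside the 35 lists. Among these runs were genes for oxidation of alcohols: exaA, the ethanol dehydrogenase that uses pyrroloquinoline quinone, exaB, exaC and pqqA had a median log2 fold change of 3.76 in tap water and 4.34 in pond water, and -0.37 in dilute LB. In pond water the run went on through pqqB, pqqC and pqqD, genes for making that cofactor. The periplasmic nitrate reductase genes napC, napB, napA and napD rose in pond water with a median of 2.7 (1.58 in tap water), while narG, narH, narJ and narI of the membrane-bound nitrate reductase, not a run, fell there with log2 fold changes of -0.61, -2.07, -1.51 and -3.20. PA1760 to PA1763 had a median of 5.03 in pond and 3.45 in tap water, and PA4504 to PA4508, which include genes of a transporter, of 3.04 and 1.89.

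The run opdT, PA2506, catA and catC, of which catA and catC act in catechol breakdown, had a median of 4.08 in tap water and 0.70 in pond water, and of 3.40 in the direct comparison. Picked by hand, the genes of the sigma factor locus PA3410, PA3411 and PA3412 were higher in tap than in pond water by 5.54 ± 0.13, 4.66 ± 0.09 and at least 4.97 on the log2 scale, PA3412 being at background in pond water (3.27). Ferrous iron uptake genes PA4358 and PA4359 fell in both waters, by log2 fold changes of -2.97 and -4.11 in tap water and -3.02 and -4.21 in pond water, and in dilute LB by -2.28 and -1.89. Among quorum sensing genes lasI rose by 2.78 in tap and 3.28 in pond water and rhlR by 1.46 and 1.51, while hcnA, hcnB and hcnC fell with log2 fold changes of -1.5, -2.01 and -2.20 in tap water and -1.56, -2.12 and -2.03 in pond water; the levels of hcnA in the waters, 3.03 and 2.98, lay at background, so its fall is a lower bound.

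Ribosomal protein genes were lower in both waters than in dilute R2B. Their fall exceeded that of probe sets of like level by -1.34 in tap and -1.93 in pond water (median difference from the 20 nearest probe sets), which argues against a normalization that depends on intensity. Against dilute LB the list medians were -1.28 and -1.77, which argues against dilute R2B arrays that stand apart. This follows from the small difference of the list in dilute LB against dilute R2B (median -0.05), so it is no separate evidence. The hibernation genes rmf and PA4463 rose in both waters, the smallest of the 4 changes being 0.64 (PA4463 in tap water), so slowed growth with ribosomes held inactive may underlie the pattern. The arrays carry no measure of growth or of RNA per cell, so this stays a hypothesis.

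Copper and zinc efflux genes were higher in tap than in pond water. The lowest tap water array lay above the highest pond water array by 2.72 in the mean of the copper list and 2.92 in that of the zinc list, which argues against a single tap water array as the cause. The sample labels name no separate collections of either water, so a feature of a single collection is not excluded. More copper in the tap water is a candidate explanation. However, oprC, a copper channel gene that copper is known to lower, differed by only -0.21 ± 0.12 (adjusted p = 0.26). Against dilute R2B it had fallen in both waters (-1.72 and -1.5). It was also lower in dilute LB (-0.83 ± 0.13, adjusted p = 2.8e-03), where the copper list did not rise. The gene therefore left the question open. For zinc, 3 of the 30 zinc starvation genes were lower in tap water, among them znuC at -0.74 (adjusted p = 7.2e-04). The list was not called between the waters, with a mean level of 4.78 in tap and 4.86 in pond water. The other znuABC genes, PA5498 and znuB, stood only 1.38 and 1.65 above the highest control value in pond water. They had little room to fall. Copper, zinc and another stress that induces both sets therefore cannot be told apart here.

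Glycine betaine catabolism genes were higher in pond water than in dilute R2B. Against dilute LB 20 of the 24 members were called higher, which argues against dilute R2B arrays that stand apart. Only 5 of the 24 members were called between dilute LB and dilute R2B, so this largely follows from that comparison. The choline-induced genes betA, betB and betI rose with a median of 2.09 in pond water, as foreseen if choline or a compound that yields it was present. At least betB is itself a member of the list, so this rise is partly the pattern and cannot decide its source. Choline stays a candidate only. In dilute LB betA, betB and betI rose further, betB by 4.86 and betI by 4.05. There gbcA had a log2 fold change of -0.26 ± 0.10 (adjusted p = 0.18) and 5 of the 24 members rose in all. A rise of the bet genes thus did not go with a rise of the whole list in dilute LB. Betaine or carnitine in the pond water was not tested.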
